A study of Homo sapiens with 9 samples.

How the data were processed

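Messenger RNA of SUM-44PE cells was sequenced in 9 libraries, 3 each for the LacZ hairpin, shASH2L-275 and shASH2L-276. Cells were selected with puromycin after lentiviral transduction, per the labels' protocols. The authors deposited 3 tables, 1 for each hairpin against LacZ and 1 for both hairpins together. Each table holds 25375 gene rows with whole-number counts per gene and library, which the authors deposited without normalization, as the values show. TopHat2, HTSeq and DESeq2 with the build hg19 are named, per the submitters' processing notes, without versions, settings or a statement on strand. Each table also holds the authors' log2 fold changes with standard errors, as deposited, in the column layout of DESeq2. The p-values and adjusted p-values in the tables are those of the authors' comparison, as deposited, and are missing for genes without a test. The authors' pooled table holds 7 libraries and lacks shASH2L-276 replicates B and C. No coordinates are given, since the reference at hand (RefSeq gene table of GRCh38.p14, GENCODE release 29) is of another build. The hairpin sequences are not given in the sources used here.

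The deposited counts were analysed again. Total counts ran from 43867777 to 49363491 per library, and 4450 rows had no count in any library. Genes were filtered with filterByExpr (minimum count 10) of edgeR 4.0.16, which left 14852 genes with 99.98% of the counts and removed 10523. Libraries were scaled by TMM (factors 0.964 to 1.03) and fitted in R 4.3.3 with the robust quasi-likelihood model of edgeR on all 9 libraries, without covariates. The common biological coefficient of variation was 3.75%. The contrasts were the mean of both hairpins minus LacZ, each hairpin minus LacZ, and shASH2L-276 minus shASH2L-275. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and standard errors were taken from the F statistic. The level of ASH2L was compared by an exact permutation test.

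The design, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. The rule took, for both hairpins, the 12 largest rises and 12 largest falls among genes with a symbol and a mean of at least 50 normalized counts. These had to pass in the pooled contrast and with each hairpin in the same direction, without overlap of knockdown and LacZ values. For each other contrast it took the 5 largest rises and falls above the same floor, and from each list up to 4 members with the smallest adjusted p. ASH2L and a fixed set of marker genes were added. Some genes that the rule took are not reported here. The lists covered COMPASS/MLL subunits, other chromatin regulators, the 8p11-p12 amplicon, FGFR/MAPK targets, HOX genes, estrogen response, luminal, basal and mesenchymal genes, S phase, G2/M, p53 targets, MYC and ribosome biogenesis, ribosomal proteins, histones, cholesterol synthesis, hypoxia and glycolysis, stress responses, interferon, NF-kB, and leukocyte, fibroblast and endothelial markers. The mitochondrial genome list could not be tested, as none of its 13 members is in the tables. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, also with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over the 23 lists within a contrast.

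Overlap between hairpins was set against independent lists and 20 simulated draws of unchanged groups. All 9 libraries were drawn from the LacZ means, a simulation chosen after seeing the data. The planned simulation, which kept the LacZ counts and drew the rest around their means, left out the error that shared controls bring, so its values were not used. Words of 7 bases in 3' UTRs of GENCODE release 29 were tested against fold changes of 12985 genes, with UTR length, GC content and level as covariates and 100 permutations. This used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The alternatives were DESeq2 1.42.0 (size factors, Wald test), other filters and thresholds, total-count scaling, a replicate block and leaving out each library. They also included other sets of libraries, the authors' tables and genes without 4 of the associated words.

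The gene tests were tested on simulated counts for 14852 genes, of which 200 were changed. For both hairpins against LacZ, where 14699 genes passed the filter, edgeR recovered 50% of genes changed by 0.2 on the log2 scale, 83.0% at 0.5, 93.9% at 1 and 100% at 2. For shASH2L-275 the shares over the same 14699 genes were 38%, 83.0%, 87.8% and 100%, and for shASH2L-276 26%, 80.9%, 89.8% and 100%. Of the calls, 5.39%, 5.10% and 5.92% were unchanged genes. With no gene changed, edgeR called 1 gene in each contrast. For both hairpins against LacZ, camera called a list of 30 members raised by 0.5 and 0 of 20 unchanged lists. The word test, for shASH2L-276 on 12985 genes, ranked 20 of 20 planted words first.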

Results

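The series profiled messenger RNA by sequencing in SUM-44PE, an estrogen receptor-positive luminal breast cancer cell line with amplification of the 8p11-p12 region. The question was which genes depend on ASH2L. ASH2L, whose gene lies in that region, is a core subunit of the COMPASS/MLL complexes that methylate lysine 4 of histone H3. Cells carried a lentiviral short hairpin RNA against ASH2L (shASH2L-275 or shASH2L-276) or against LacZ, a bacterial gene used as the control. Each of the 3 groups had 3 libraries described as biological replicates (A, B and C). The 9 libraries held between 43867777 and 49363491 gene counts, and 14852 of 25375 gene rows were tested. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom between 2.63 and 9.12. None was therefore counted as a duplicate. That excess does not show separate cultures, so the p-values here measure the spread between libraries of a group. Any difference between cultures that came with a hairpin cannot be told apart from that hairpin's effect.

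ASH2L (GeneID 9070 in the files) was lower with each hairpin. Its level was 851 ± 15.6 CPM (counts scaled to the total of the library, TMM-adjusted) in the LacZ libraries (SD, n = 3), 41.9 ± 1.30 with shASH2L-275 and 134 ± 7.90 with shASH2L-276, so that 4.92% and 15.8% of the control level remained. The log2 fold changes were -4.35 ± 0.044 (SE) and -2.66 ± 0.040, and -3.50 ± 0.033 for both hairpins together (edgeR adjusted p = 2.01e-26). All 6 knockdown libraries lay below the 3 LacZ libraries (exact permutation test over 84 splits, one-sided p = 0.0119, two-sided p = 0.0238), and 3 against 3 libraries cannot go below p = 0.1. The authors' deposited table of both hairpins together, which holds 7 libraries, gives a log2 fold change of -2.01 with a standard error of 0.354. Their tables of each hairpin give -4.33 and -2.65. The pooled value is smaller in size than either, so the choice of libraries alone does not account for it. The cause was not tested, and the value may not be of the same measure as those given here.

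**Figure D1:**
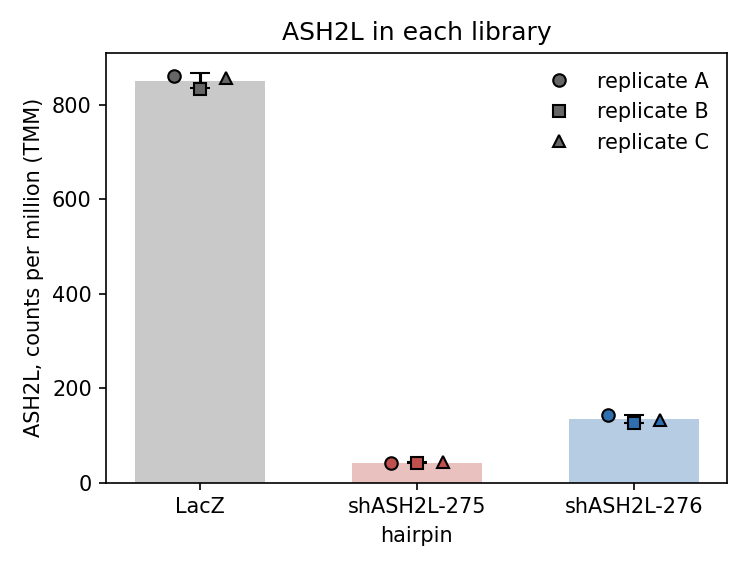
ASH2L in CPM for each of the 9 libraries (points), with the group mean (bars) and SD (error bars, n = 3), by hairpin. The LacZ mean is 851, against 41.9 with shASH2L-275 and 134 with shASH2L-276.

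The first comparison asked which genes changed when both hairpins were set against LacZ. Most tested genes of the S phase (35 of 35), G2/M (40 of 42), ribosomal protein (34 of 38) and estrogen response (23 of 34) lists were lower, and most of the hypoxia and glycolysis list (22 of 30) were higher. These lists passed camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.269 to 0.384). Among the genes with the largest changes shared by both hairpins, S100P, a calcium-binding protein, rose from 4.92 CPM in LacZ to 17.9 and 88.8 (log2 fold change 3.02 ± 0.13, edgeR adjusted p = 1.21e-08). ELOVL2, an elongase of very long chain fatty acids, fell from 59.9 to 10.2 and 15.1 (-2.27 ± 0.045, edgeR adjusted p = 3.1e-20). AGR2, a disulfide isomerase of the endoplasmic reticulum, fell from 195 to 22.1 and 103 (-2.03 ± 0.034, edgeR adjusted p = 1.65e-21). In all, 4643 genes were higher and 5029 lower, of which 424 and 375 changed at least 2-fold.

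The pooled log2 fold changes were 2.78 for the tetraspanin TSPAN7, 2.76 for the aspartyl protease BACE2, 2.46 for HKDC1, a hexokinase relative, and 2.45 for the engulfment adaptor GULP1. ATG9B, a membrane protein of autophagy, rose by 2.34, PLA2G10, a secreted phospholipase, by 2.20, the secreted factor FAM3C by 2.13 and ALDH1A1, a retinaldehyde dehydrogenase, by 2.05. TREML2, TREML3P and TREML4, relatives of the TREM receptors, rose by 3.02, 2.33 and 2.03. These 3 are neighbours and related in sequence, so reads could be shared between them, and their values are uncertain. On the falling side, the lipid droplet protein PLIN5 changed by -2.56, the netrin NTN3 by -2.49, ZMYND10, an assembly factor of ciliary dynein arms, by -2.25 and ARC, an immediate early gene of neurons, by -2.17. TAT, which degrades tyrosine, changed by -2.07, the corneocyte adhesion protein CDSN by -2.06, MS4A7 by -2.04, the alkaline phosphatase ALPL by -2.03 and the scaffold protein MPP2 by -1.97. Each of these genes passed with each hairpin alone, in the same direction, with no overlap between the 6 knockdown and 3 LacZ values.

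**Figure D2:**
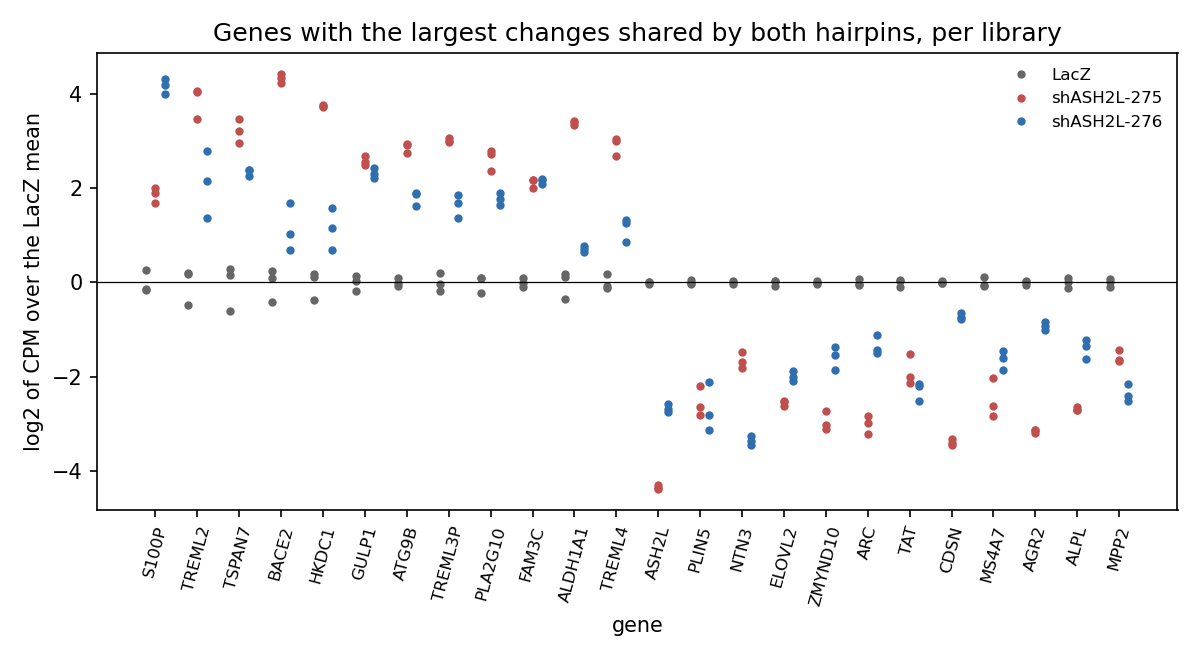
Level in each library relative to the LacZ mean (vertical axis, log2 of CPM over that mean) of the 12 genes highest and the 12 lowest with both hairpins. ASH2L is among the falling genes at -4.35 and -2.66, and S100P rose more with shASH2L-276 (4.17) than with shASH2L-275 (1.87).

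Cell cycle genes fell as groups. Of the 35 tested S phase genes, all 35 fell, with a median log2 fold change of -0.91 (camera adjusted p = 2.33e-20, adjusted p = 0.269 with an estimated correlation). UHRF1, which links DNA methylation to replication, fell by 1.75 ± 0.043 on the log2 scale, the helicase subunits MCM6 and MCM3 changed by -1.10 ± 0.027 and -1.01 ± 0.028, and the transcription factor E2F1 by -1.14 ± 0.033. Of the 42 G2/M genes, 40 fell, none rose and 2 did not pass (41 lower adjusted over the list alone), with a median of -0.60 (camera adjusted p = 1.17e-12, adjusted p = 0.384 with an estimated correlation). Examples were UBE2C, an enzyme of mitotic protein degradation (-0.87 ± 0.039), and the spindle checkpoint kinase BUB1B (-0.93 ± 0.057). The proliferation marker MKI67 changed by -0.91 ± 0.12 and CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.06 ± 0.038. Among p53 targets 14 of 25 rose, 7 fell and 4 did not pass, and the list did not pass (camera adjusted p = 0.0596, adjusted p = 0.269 with an estimated correlation). It passed without shASH2L-276 replicate C (adjusted p = 0.0468). TP53I3, an oxidoreductase gene induced by p53, rose by 1.16, and the nuclease AEN changed by -0.51.

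Ribosomal protein genes fell: 34 of 38 were lower, 1 was higher and 3 did not pass, with a median of -0.26 (camera adjusted p = 1.04e-07, adjusted p = 0.384 with an estimated correlation). RPL22 changed by -0.56 ± 0.026 and RPS2 by -0.60 ± 0.035. Among genes of MYC and ribosome biogenesis, 5 of 34 rose, 20 fell and 9 did not pass (camera adjusted p = 0.0302, adjusted p = 0.384 with an estimated correlation). With shASH2L-276 alone this list went both ways, 15 higher and 11 lower (median 0.0066, camera adjusted p = 0.88, adjusted p = 0.91 with an estimated correlation). The nucleolar proteins NOLC1 and FBL changed by -0.62 and -0.47, while MYC itself rose by 0.54. In the estrogen response list, 6 of 34 rose, 23 fell and 5 did not pass (adjusted over the list alone, 7 higher and 23 lower), with a median of -0.35 (camera adjusted p = 9.57e-05, adjusted p = 0.269 with an estimated correlation). With shASH2L-276 alone this list did not pass, 9 higher and 19 lower (median -0.10, camera adjusted p = 0.146, adjusted p = 0.547 with an estimated correlation). The protease inhibitor SERPINA3 changed by -1.47, the growth factor-binding protein IGFBP4 by -0.99 and the cochaperone FKBP4 by -0.73. These 3 were higher with shASH2L-276 than with shASH2L-275 by 1.36, 1.77 and 1.49, so their pooled values do not hold for each hairpin. ESR1, the estrogen receptor, changed by -0.41 ± 0.044. Its partner factors GATA3 and FOXA1 changed by -1.01 ± 0.051 and -0.40 ± 0.039, and cyclin D1 (CCND1) by -0.35 ± 0.027. ESR1 and GATA3 fell further with shASH2L-275 alone than in the pooled contrast, so their pooled values do not hold for each hairpin either. PGR, the progesterone receptor, did not pass (0.22 ± 0.10, edgeR adjusted p = 0.0586) but did without shASH2L-275 replicate B (adjusted p = 0.0349) or LacZ replicate A (0.0116), and with no filter on low counts (0.0381).

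In the luminal epithelial list, 7 of 18 rose, 8 fell and 3 did not pass, and its median (0.042) and mean (-0.23) differed in sign (camera adjusted p = 0.42, adjusted p = 0.589 with an estimated correlation). The keratins KRT8, KRT19 and KRT18 changed by -0.81, -0.73 and -0.55. In the basal and myoepithelial list, 9 of 13 rose, 2 fell and 2 did not pass (camera adjusted p = 0.0309, adjusted p = 0.269 with an estimated correlation), with P-cadherin (CDH3) at 0.40 and the receptor EGFR at 1.54. CAV1 and CAV2, in the same list, held 1 count each over the LacZ libraries, so no fold is given. The median was 0.40 with them and 0.23 without them, and the call was lost when any of 8 single libraries was left out (all but LacZ replicate A), with an adjusted p of up to 0.0804 and a median down to 0.20 (without shASH2L-276 replicate C or shASH2L-275 replicate B). The filter on low counts was run again for each of these fits, so the members tested can differ. The EMT list had 5 members higher, 5 lower and 5 not passing (camera adjusted p = 0.845, adjusted p = 0.919 with an estimated correlation), with opposite signs of its median (-0.069) and mean (0.20). E-cadherin (CDH1) changed by -0.15 and vimentin (VIM), near 1.94 CPM in LacZ, by -0.58. The VIM call was lost without LacZ replicate A (edgeR adjusted p = 0.0574).

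Groups that rose included hypoxia and glycolysis, where 22 of 30 rose, 2 fell and 6 did not pass (adjusted over the list alone, 23 higher and 2 lower), with a median of 0.24 (camera adjusted p = 5.65e-05, adjusted p = 0.384 with an estimated correlation). Lactate dehydrogenase LDHA rose by 0.64 ± 0.029, the glucose transporter SLC2A1 by 0.67 ± 0.032 and the kinase PDK1 by 0.68 ± 0.042. In the unfolded protein and integrated stress response list, 23 of 38 rose, 9 fell and 6 did not pass (camera adjusted p = 0.0309, adjusted p = 0.384 with an estimated correlation). With shASH2L-275 and shASH2L-276 alone the list did not pass (camera adjusted p = 0.1 and 0.146). Its members HERPUD1, which acts in degradation of misfolded proteins, and the chaperone DNAJB9 rose by 0.79 and 0.85, while the folate enzyme MTHFD2 and the secreted hormone STC2 changed by -0.60 and -0.66. In the interferon list, 20 of 33 rose, 6 fell and 7 did not pass, with a median of 0.43 (camera adjusted p = 0.00244, adjusted p = 0.384 with an estimated correlation), and IFIT2, which binds viral RNA, rose by 1.49 ± 0.075. In the NF-kB and cytokine list, 10 of 17 rose, 3 fell and 4 did not pass (camera adjusted p = 0.0317, adjusted p = 0.384 with an estimated correlation), with the apoptosis inhibitor BIRC3 at 1.47 ± 0.081. All 4 tested leukocyte markers rose (camera adjusted p = 0.0259, adjusted p = 0.269 with an estimated correlation): CD68 by 0.99, CD163 by 1.99, CD14 by 1.16 and CSF1R by 1.36. With shASH2L-276 alone, 3 of these 4 markers rose and 1 did not pass. The interferon, NF-kB and leukocyte lists did not pass with that hairpin alone (camera adjusted p = 0.715, 0.881 and 0.146). The other 8 leukocyte markers were too low to test, with at most 4 counts for PTPRC, the pan-leukocyte phosphatase, and 9 for LYZ in any library.

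Among COMPASS/MLL complex genes, 2 of 20 rose, 10 fell and 8 did not pass (adjusted over the list alone, 2 higher and 9 lower), ASH2L among the falling ones (camera adjusted p = 0.0309, adjusted p = 0.384 with an estimated correlation). The call was lost without LacZ replicate B (adjusted p = 0.0559). The list median was -0.087 and its mean -0.31. ASH2L, at -3.50, is the target of the hairpins, and the list was not tested without it, so the call does not speak for the other subunits. PAXIP1 and PAGR1, partners within some MLL complexes, changed by -0.58 and -0.40, and the chromatin reader PSIP1 by -0.65. In the list of H3K4 demethylases and other chromatin regulators, 4 of 26 rose, 14 fell and 8 did not pass (camera adjusted p = 0.0394, adjusted p = 0.384 with an estimated correlation), a call lost without shASH2L-275 replicate B (adjusted p = 0.0530), LacZ replicate B (0.0729) or LacZ replicate C (0.0530). With shASH2L-275 and shASH2L-276 alone the list did not pass (camera adjusted p = 0.1 and 0.0857). It passed without LacZ replicate A with each (adjusted p = 0.0474 and 0.0295), and with shASH2L-276 also without its replicate A (0.0436). The members named by the rule were the maintenance DNA methyltransferase DNMT1 (-0.67), the H3K9 methyltransferase EHMT2 (-0.63), the H3K36 methyltransferase WHSC1 (-0.67) and the H3K4 demethylase KDM5B (0.58).

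The remaining lists did not pass. In the 8p11-p12 amplicon list, 11 of 20 rose, 8 fell and 1 did not pass (camera adjusted p = 0.463, adjusted p = 0.524 with an estimated correlation), with DDHD2 and ADAM9 at 0.43 and 0.39, and ERLIN2 at -0.38. Its median (0.10) and mean (-0.14) differed in sign, and ASH2L is a member. Cholesterol synthesis genes went both ways (9 higher, 8 lower, and adjusted over the list alone 10 and 8, camera adjusted p = 0.75, adjusted p = 0.919 with an estimated correlation), with INSIG1 and STARD4, genes of sterol sensing and transport, at -0.51 and 1.07. So did FGFR/MAPK targets (8 higher, 6 lower, camera adjusted p = 0.75, adjusted p = 0.812 with an estimated correlation), which included EGR3 at -1.88 and DUSP4 at 0.26. Of the histone list, 6 of 10 rose, 2 fell and 2 did not pass (adjusted over the list alone, 7 higher and 2 lower, camera adjusted p = 0.0847, adjusted p = 0.384 with an estimated correlation). HIST1H2BK and HIST1H1C rose by 1.05 and 1.01, and H1F0, a replication-independent linker histone, changed by -0.25. In the HOX list, 1 of 18 rose, 9 fell and 8 did not pass (adjusted over the list alone, 1 higher and 8 lower, camera adjusted p = 0.362, adjusted p = 0.515 with an estimated correlation), with HOXB5 at -0.57, HOXC4 at -0.43 and HOXD8 at -0.50. The HOXD8 call was lost without LacZ replicate B (edgeR adjusted p = 0.0726). The hairpins differed: with shASH2L-275 2 HOX genes rose and 11 fell (3 and 11 adjusted over the list alone). The median there was -0.33 (camera adjusted p = 0.189, adjusted p = 0.389 with an estimated correlation). With shASH2L-276 6 rose and 3 fell (median 0.090, camera adjusted p = 0.889, adjusted p = 0.91 with an estimated correlation). HOXB5 was higher with shASH2L-276 than with shASH2L-275 by 1.82. Of fibroblast markers, 2 of 5 rose, 1 fell and 2 did not pass, and the median (-0.32) and mean (0.048) differed in sign (camera adjusted p = 0.968, adjusted p = 0.969 with an estimated correlation). Of endothelial markers, all 3 tested fell, VWF by 0.18, CLDN5 by 1.12 and EGFL7 by 0.18 on the log2 scale (camera adjusted p = 0.343, adjusted p = 0.401 with an estimated correlation). These calls were lost without LacZ replicate A (edgeR adjusted p = 0.0512, 0.0882 and 0.107), that of VWF also without LacZ replicate C (0.0505) and that of EGFL7 also without shASH2L-275 replicate A (0.0580).

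For each list named above without such a count, the counts adjusted over the list alone were the same. Across the 23 lists, 13 passed with the preset correlation, 6 up and 7 down, and camera with an estimated correlation called 0, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.269. The same samples gave 19 lists past the threshold by fry. That test asks only whether the genes of a list changed, without setting them against other genes, and 65.1% of all tested genes were called here. With the 6 knockdown libraries as 1 group, so that the difference between hairpins entered the spread, 37 of the named genes lost their edgeR call, with an adjusted p from 0.0519 for EHMT2 to 0.716 for HOXB5. Among them were ESR1 (0.221), CCND1 (0.114), AGR2 (0.0681), CDSN (0.142), ALDH1A1 (0.0526), E2F1 (0.0724), MYC (0.0629), IGFBP4 (0.303), FGFR1 (0.614) and VIM (0.355).

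**Figure D3:**
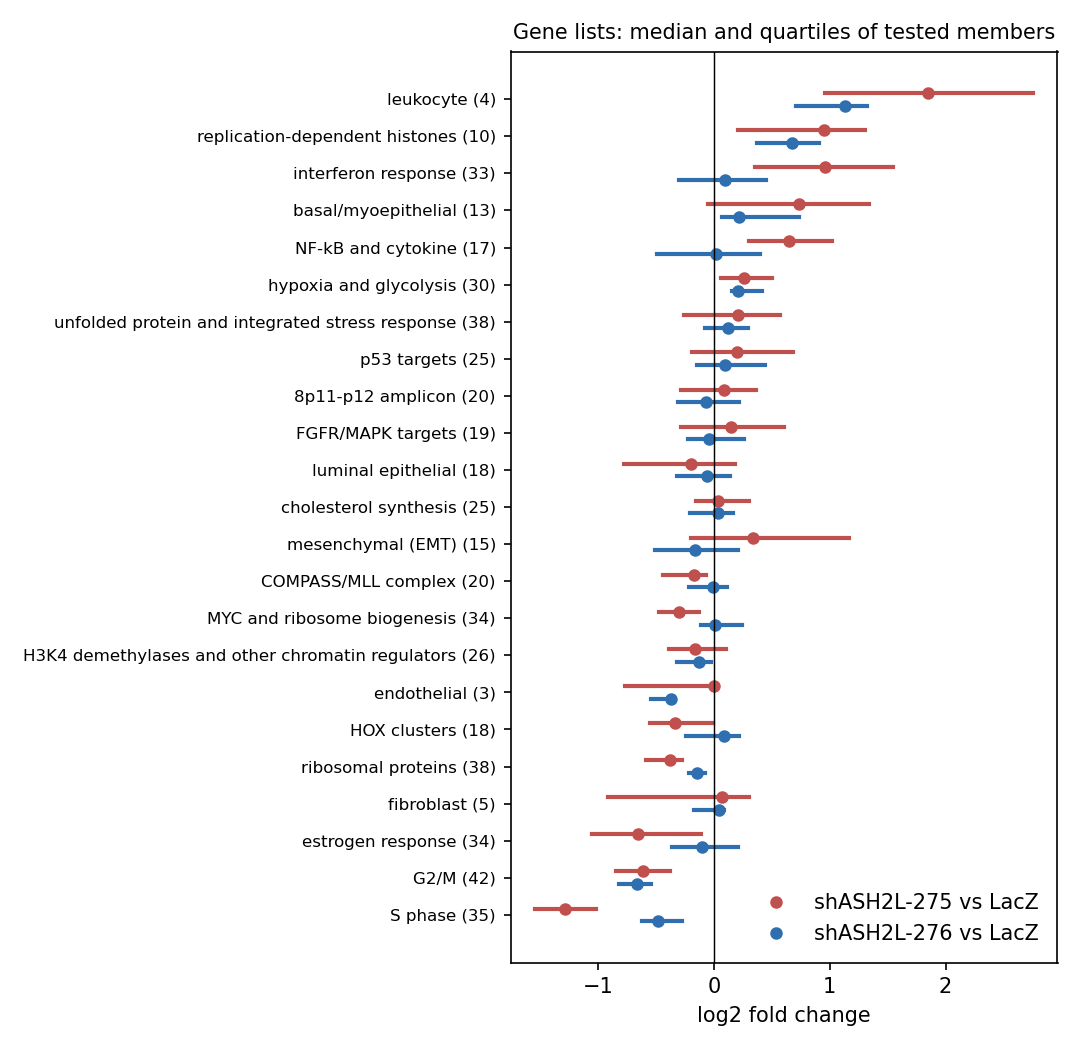
Median (points) and quartiles (bars) of the log2 fold change of the tested members of each of 23 gene lists, for each hairpin against LacZ; the number of tested members is in parentheses. The S phase medians are -1.28 and -0.48, and the interferon medians 0.96 and 0.10.

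The second comparison set shASH2L-275, the hairpin with less ASH2L left, against LacZ. BACE2 rose from 0.273 to 5.49 CPM (4.33 ± 0.20, edgeR adjusted p = 1.23e-14). The matrix-associated factor NOV, TREML2 and HKDC1 rose by 3.90, 3.86 and 3.73. Apart from ASH2L, the falls were led by CSF3R, the receptor of granulocyte colony-stimulating factor (-3.73 ± 0.25), CDSN (-3.39 ± 0.048), AGR2 (-3.14 ± 0.045) and the Fc receptor-like gene FCRLB (-3.08 ± 0.16). Interferon genes rose, 25 of 33 with 5 lower and a median of 0.96 (camera adjusted p = 5.29e-05, adjusted p = 0.282 with an estimated correlation). They included IFIT2 at 2.21, the RNA sensor IFIH1 at 1.21, SAMD9 at 1.97 and OAS2, which makes oligoadenylates, at 1.56. NF-kB genes also rose, 13 of 17 with 1 lower (camera adjusted p = 0.00118, adjusted p = 0.282 with an estimated correlation). They included CSF1, the macrophage growth factor, at 2.24. The leukocyte markers CD163 and CSF1R were at 2.71 and 2.88, with PTPRC at no more than 4 counts.

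With shASH2L-275, all 35 S phase genes fell (median -1.28, camera adjusted p = 8.66e-19, adjusted p = 0.183 with an estimated correlation). Of G2/M genes 38 of 42 fell (median -0.61, camera adjusted p = 3.53e-08, adjusted p = 0.389 with an estimated correlation). Of ribosomal protein genes 36 of 38 fell (camera adjusted p = 1.93e-08, adjusted p = 0.389 with an estimated correlation), of MYC and ribosome biogenesis genes 25 of 34 (camera adjusted p = 0.000216, adjusted p = 0.234 with an estimated correlation) and of estrogen response genes 24 of 34, with 3 higher (median -0.66, camera adjusted p = 2.77e-06, adjusted p = 0.183 with an estimated correlation). ESR1 changed by -0.75 ± 0.052 and GATA3 by -1.51 ± 0.062. In total 5206 genes were higher and 5361 lower, 922 and 839 of them at least 2-fold. By camera 12 of 23 lists passed, and 0 with an estimated correlation (lowest adjusted p = 0.183). The counts adjusted over the list alone were the same for each list named here. The p53 target list passed (median 0.20, camera adjusted p = 0.0438, adjusted p = 0.234 with an estimated correlation) but not without shASH2L-275 replicate A (adjusted p = 0.0565) or LacZ replicate B (0.0576). The basal list passed (median 0.73, camera adjusted p = 0.0438, adjusted p = 0.234 with an estimated correlation) but not without any single library other than LacZ replicate A, with an adjusted p of up to 0.124. Its median was 0.21 without shASH2L-275 replicate B, 0.33 without replicate A, 0.30 without replicate C and 0.28 without any single shASH2L-276 library. Without CAV1 and CAV2 it was 0.28. The filter on low counts was run again for each set of libraries, so the members tested can differ. The levels with shASH2L-276 are no part of this contrast, so these shifts need not reflect the values of single libraries.

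The third comparison set shASH2L-276 against LacZ. S100P (4.17 ± 0.13), the cancer-testis gene LEMD1 (2.46 ± 0.16), TSPAN7 (2.33 ± 0.25), GULP1 (2.31 ± 0.13) and TREML2 (2.18 ± 0.41) led the rise. NTN3 (-3.34 ± 0.19), GSTA2, a glutathione transferase (-3.10 ± 0.23), PLIN5 (-2.61 ± 0.20) and MPP2 (-2.36 ± 0.13) led the fall with ASH2L. GSTA2 has close paralogs, so its counts are uncertain. Of S phase genes 34 of 35 fell (median -0.48, camera adjusted p = 4.03e-13, adjusted p = 0.547 with an estimated correlation) and of G2/M genes 40 of 42 (median -0.66, camera adjusted p = 1.13e-13, adjusted p = 0.547 with an estimated correlation). UHRF1 was at -0.98 ± 0.049 and BUB1B at -1.07 ± 0.068. Hypoxia and glycolysis genes rose, 22 of 30 (camera adjusted p = 0.00142, adjusted p = 0.547 with an estimated correlation), and ribosomal protein genes fell, 22 of 38 (camera adjusted p = 0.00156, adjusted p = 0.685 with an estimated correlation). Interferon genes went both ways, 12 higher and 9 lower (camera adjusted p = 0.715, adjusted p = 0.91 with an estimated correlation), and so did estrogen response genes, 9 higher and 19 lower (camera adjusted p = 0.146, adjusted p = 0.547 with an estimated correlation). In total 4619 genes were higher and 4431 lower, 313 and 465 of them at least 2-fold. By camera 4 of 23 lists passed, and 0 with an estimated correlation (lowest adjusted p = 0.547). Lists that passed with both hairpins together but not here also included COMPASS/MLL complex (camera adjusted p = 0.301), NF-kB and cytokine (0.881), leukocyte (0.146) and basal genes (0.146). The counts adjusted over the list alone were 22 higher and 5 lower for the hypoxia and glycolysis list (against 22 and 4), 12 higher and 10 lower for the interferon response list (against 12 and 9) and the same for the other lists named here.

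The fourth comparison set the hairpins against each other. The uncharacterized transcript LOC101927136 (-4.08 ± 0.083 for shASH2L-276 minus shASH2L-275), the carboxylesterase CES1 (-3.94 ± 0.064), the cytokine IL32 (-3.80 ± 0.15) and NOV (-3.63 ± 0.19) were lower with shASH2L-276. CSF3R (3.81 ± 0.25), ODAM (3.39 ± 0.26), the transporter ABCC12 (2.95 ± 0.14), EFCAB4B (2.84 ± 0.12) and the clotting factor subunit F13A1 (2.83 ± 0.15) were higher. CES1 rose with shASH2L-275 (3.18) and fell with shASH2L-276 (-0.75), and FGFR1, a receptor gene of the 8p11-p12 region, did likewise (0.58 and -0.32). S phase genes were higher with shASH2L-276, 34 of 35 (median 0.85, camera adjusted p = 6.9e-13, adjusted p = 0.386 with an estimated correlation). Estrogen response genes were also higher, 25 of 34 (median 0.55, camera adjusted p = 6.5e-06, adjusted p = 0.35 with an estimated correlation). Interferon genes were lower, 23 of 33 (median -0.76, camera adjusted p = 8.09e-05, adjusted p = 0.435 with an estimated correlation), and NF-kB genes, 14 of 17 (camera adjusted p = 0.00318, adjusted p = 0.435 with an estimated correlation). G2/M genes did not differ as a list (median -0.024, camera adjusted p = 0.596, adjusted p = 0.933 with an estimated correlation), but without shASH2L-276 replicate A the list passed (median -0.20, adjusted p = 0.0306). In total 5372 genes were higher and 5215 lower with shASH2L-276, 679 and 957 of them at least 2-fold. The counts adjusted over the list alone were 26 higher and 5 lower for the estrogen response list (against 25 and 5), 7 higher and 11 lower for the G2/M list (against 7 and 12) and the same for the other lists named here.

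Genes that moved with both hairpins numbered 2490 higher and 2431 lower, against 1619 and 1599 for independent lists of the same sizes. The simulated unchanged groups gave an overlap of at most 1 gene and at most 5 calls, so they give no scale for the overlap. Of the 7086 genes called with both, 4921 went the same way and 2165 (30.6%) went opposite ways, 984 higher with shASH2L-275 and lower with shASH2L-276, and 1181 the reverse. Of the genes with the same direction, 66.1% changed more with shASH2L-275. Over all tested genes, which are not independent replicates, the fold changes had a Pearson r of 0.37 and a Spearman rho of 0.35. Both were below those of simulated unchanged groups that share controls (0.51 and 0.449). Those groups hold only noise, which shared controls correlate whatever its size, so they give no scale for r or rho. The covariance was 0.128, against a mean of 0.013 and at most 0.0145 over 20 simulated draws, so it was above what shared controls gave there. The 3 controls were too few to split, so part of the excess over independent lists may come from the shared controls. The first principal component (59.0% of the variance) set shASH2L-275 apart from the other groups, and the second (25.8%) set LacZ apart from shASH2L-276.

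**Figure D4:**
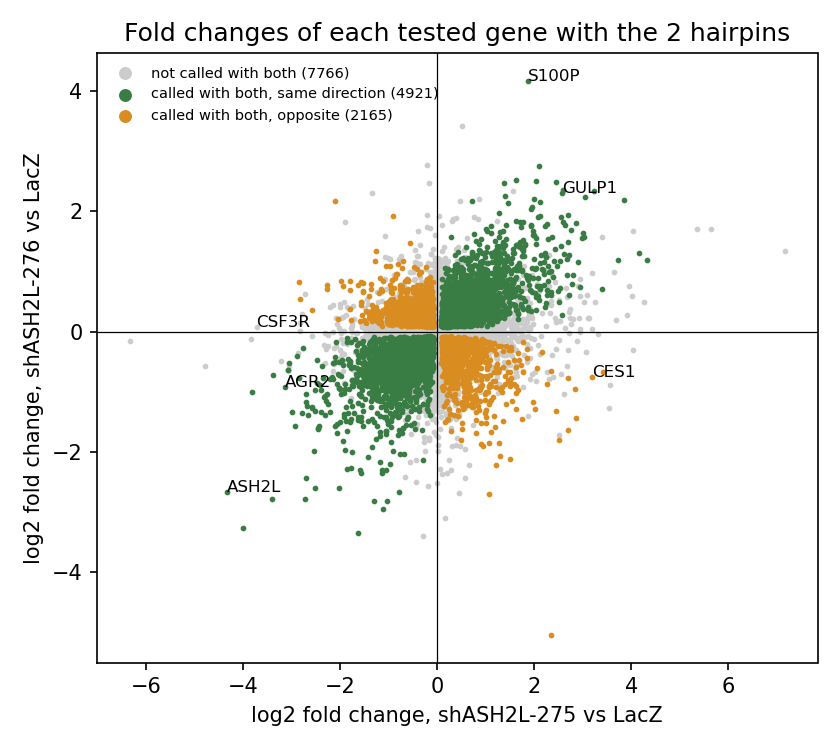
Log2 fold change of each tested gene with shASH2L-275 (horizontal axis) and shASH2L-276 (vertical axis) against LacZ; colours mark genes called with both hairpins in the same (4921) or opposite (2165) direction. S100P lies at 1.87 and 4.17, and ASH2L at -4.35 and -2.66.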

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

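Some tests of this part were chosen only after the results were seen. They were those of the graded response, both hairpin seeds, growth state, leukocytes, shASH2L-275 itself and the other splits of the libraries. The tests of the 4 words as the whole cause and of the S phase list against base content and words preceded their outcome. The patterns they address had been seen, and the 4 words were picked from the same fold changes.

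What brought each result here was a tested difference between the hairpins, shASH2L-276 minus shASH2L-275. edgeR called 10587 genes, and 2165 genes were called with both hairpins in opposite directions. By camera, lists higher with shASH2L-276 were S phase (median log2 difference 0.85, camera adjusted p = 6.9e-13, adjusted p = 0.386 with an estimated correlation), estrogen response (0.55, camera adjusted p = 6.5e-06, adjusted p = 0.35 with an estimated correlation), MYC and ribosome biogenesis (0.37, camera adjusted p = 0.000535, adjusted p = 0.435 with an estimated correlation) and ribosomal proteins (0.25, camera adjusted p = 3.05e-05, adjusted p = 0.611 with an estimated correlation). Lists lower with it were the interferon response (-0.76, camera adjusted p = 8.09e-05, adjusted p = 0.435 with an estimated correlation) and NF-kB and cytokine genes (-0.55, camera adjusted p = 0.00318, adjusted p = 0.435 with an estimated correlation). Fold changes between hairpins rose with GC content (Spearman rho 0.179), and correction for GC content, length and level left a ribosomal protein median of 0.09 (quartiles -0.12 to 0.22). The corrected medians of the other 5 lists, in the order above, were 0.82, 0.50, 0.26, -0.71 and -0.57. Of 129 named genes, 112 differed, 45 of them at least 2-fold, 22 higher and 23 lower with shASH2L-276.

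ASH2L itself was higher with shASH2L-276 by 1.68 on the log2 scale. The other named genes higher by at least 2-fold, with the log2 difference, were S100P (2.31), LEMD1 (1.08), CSF3R (3.81), ODAM (3.39), ABCC12 (2.95), EFCAB4B (2.84), F13A1 (2.83), ZMYND10 (1.37), ARC (1.66), CDSN (2.67) and AGR2 (2.22). To these add ALPL (1.28), FCRLB (2.44), SERPINA3 (1.36), IGFBP4 (1.77), FKBP4 (1.49), EGR3 (1.68), HOXB5 (1.82), UHRF1 (1.56), E2F1 (1.31) and VIM (1.01). Named genes lower with shASH2L-276 were TREML2 (-1.67), BACE2 (-3.13), HKDC1 (-2.54), ATG9B (-1.07), TREML3P (-1.36), ALDH1A1 (-2.67), TREML4 (-1.76), NOV (-3.63), NTN3 (-1.70), GSTA2 (-3.25), LOC101927136 (-4.08), CES1 (-3.94) and IL32 (-3.80). Also lower were INSIG1 (-1.36), STARD4 (-1.33), INSIG2 (-1.06), IFIT2 (-1.43), SAMD9 (-1.85), CD163 (-1.43), CSF1R (-3.03), FN1 (-1.37), SPARC (-1.14) and CSF1 (-1.77). Groups of 3 libraries were too small for a test of outlying libraries.

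Of the 7086 genes called with both hairpins, 30.6% went in opposite directions, a share that excludes, as the whole account, a response in which each gene moves 1 way and further with a deeper loss of ASH2L. Repression through the seed of shASH2L-276 is a candidate cause of some falls with that hairpin, and of at most part of the opposite share. Genes with ATGTTCT in the 3' UTR were lower with that hairpin (z -11.2, 2150 genes, highest permuted 5.20) and not with shASH2L-275 (z 2.61). ATGTTCT is a word of the ASH2L transcript. For shASH2L-275 no word of the ASH2L transcript passed in the same way (lowest z -4.30, TGAACGG, highest permuted 5.17). With its reverse complement, which a seed of the other hairpin strand would need, the lowest was -6.03. The strongest word, GAACGGT (z -6.85), is in neither. However, it shares the bases GAACGG with TGAACGG of the transcript and with GAACGGA (z -6.15), AGAACGG (-5.92) and GGAACGG (-5.09). Words shorter than 7 bases were not tested, so a seed effect stays open. The words with the lowest z for each hairpin (GAACGGT and GAACGGA for shASH2L-275, ATGTTCT and TGTTCTA for shASH2L-276) are not the whole cause. Of the 4834 genes called with both hairpins and without these 4 words, 30.8% went opposite ways, against 32.3% of the 1738 with any of them. These 4 words thus mark little of the opposite share. Genes without them can still carry other associated words, such as TGTTCTC (z -7.31 with shASH2L-276). Since 16.8% of words occur in the ASH2L transcript by the same search, presence there is weak evidence, and different responses to different depths of knockdown were not tested.

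S phase genes fell with both hairpins, by a median of -0.91 over 35 genes (camera adjusted p = 2.33e-20, adjusted p = 0.269 with an estimated correlation). Correction for GC content, length and level left a median of -0.94, and the 31 members without the 4 words above had a median of -0.92. Neither these covariates nor these 4 words account for the fall, and other associated words were not removed. The S phase median was below the lowest LacZ library in 6 of 6 knockdown libraries (27.5 to 29.6 CPM with shASH2L-275, 46.1 to 54.1 with shASH2L-276, 55.4 to 59.7 with LacZ). A difference in growth state of the cultures cannot be told apart from an effect of ASH2L, since cultures and hairpins coincide.

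Most tested interferon (25 of 33) and NF-kB genes (13 of 17) rose with shASH2L-275 (camera adjusted p = 5.29e-05 and 0.00118, adjusted p = 0.282 for each with an estimated correlation). The leukocyte list rose with them, 4 of 4 tested markers (median 1.85, camera adjusted p = 0.0235, adjusted p = 0.234 with an estimated correlation), CSF1R by 2.88 and CD163 by 2.71. Leukocytes among the cells are excluded as the source, with at most 4 counts of PTPRC and 9 of LYZ in any library. The interferon list was lower with shASH2L-276 by a median of -0.76, but a response to shASH2L-275 itself and a response to its deeper loss of ASH2L cannot be told apart, since each hairpin comes with 1 depth of knockdown.

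Other splits of the libraries test whether chance can account for the counts of genes. For both hairpins against LacZ, edgeR called 9672 genes and at most 3523 in the others of 100 splits, so that the real split alone (1 of 100) reached its count. That highest split kept the 3 LacZ libraries together and mixed the hairpins, so it follows the structure of the samples. No other split drawn kept the libraries of all 3 groups together, and mixed groups put the differences between groups into the spread. The splits thus exclude a chance division of the 9 libraries as a whole. They do not single out the difference between LacZ and the hairpins. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real counts there were 10567 for shASH2L-275, 9050 for shASH2L-276 and 10587 between hairpins, which the real split alone (1 of 10) reached each time, with a highest other of 0 by edgeR in each (at most 222, 464 and 444 genes at an unadjusted p under 0.05).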

How the results depend on the processing

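Total-count scaling, the fit to 7 libraries as 1 group and the count of genes without the 4 words were chosen after seeing the data. Over all alternatives, ASH2L was lower in 51 of 51 fits, and 182 of 202 counts of genes stayed within 1.5 times the main count. With a change of at least 2-fold added, the counts higher and lower were 424 and 375 for both hairpins, 922 and 839 for shASH2L-275, 313 and 465 for shASH2L-276, 679 and 957 between hairpins, and 160 and 123 shared by both hairpins. The 6 knockdown libraries as 1 group gave 2028 and 1799 genes, and 7 libraries as 1 group 2619 and 2314, as the difference between hairpins then enters the spread. The authors' pooled table gave 2778 lower genes, from the same 7 libraries, and an ASH2L log2 fold change of -2.01. Genes without the 4 words are fewer. Among them, 3346 were lower with both hairpins together, 3386 higher with shASH2L-275 and 2740 lower with shASH2L-276. Between hairpins 3193 were lower, and 1572 were lower with each. The correlation of fold changes across genes was 0.391 at a mean of at least 50 counts, and the cause was not tested. By fry, the 8p11-p12 list was called down with medians of 0.10 (both hairpins) and 0.091 (shASH2L-275). Camera gave the direction as up but did not call it (adjusted p = 0.463 and 0.549), and the cause was not tested.

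Leaving out each library gave, higher and lower, 4191 to 4593 and 4658 to 5156 genes for both hairpins, 4953 to 5275 and 5096 to 5464 for shASH2L-275, and 4091 to 4557 and 4130 to 4677 for shASH2L-276. Between hairpins it gave 4962 to 5374 and 5032 to 5285, and for genes shared by both 2236 to 2460 and 2209 to 2489. The correlation ranged from 0.353 to 0.393 and the pooled ASH2L change from -3.53 to -3.49. Of named gene results over the alternatives, 2407 stayed on the same side, 56 lost and 3 gained the call, 37 of the losses with the 6 libraries as 1 group and 12 in the authors' tables. Of list results, 1186 stayed, 57 lost the call (35 with an estimated correlation), 43 gained it (38 by fry) and 2 reversed. Total-count scaling gave 3882 higher and 5188 lower genes for shASH2L-276 and 4590 and 5944 between hairpins, so that lower genes outnumbered higher ones.

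The letters A, B and C do not pair the libraries by the data. The 9 same-letter pairs had correlations of -0.172 to 0.0881, 0 above 0.1, and 0 libraries correlated best with their own letter. A replicate block gave 4553 higher and 4943 lower genes for both hairpins, and changed no call of a named gene or list. Other pseudocounts were not run, as the files hold counts. CAV1 and CAV2, at 1 count each over the LacZ libraries, were too low for a fold change.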

Other observations

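The gene lists of this part and the test of the LacZ hairpin's seed were chosen only after results were seen. Targets of NRF2, the transcription factor of the response to oxidants, rose in the comparison of both hairpins together, 24 of 25 with 0 lower by edgeR. The median log2 fold change was 0.64 (0.85 with shASH2L-275, 0.43 with shASH2L-276, camera adjusted p = 2.6e-14, adjusted p = 0.0623 with an estimated correlation). Examples, with shASH2L-275 and shASH2L-276, were AKR1C1 (2.67 and 1.21), a reductase of steroids and aldehydes, the cystine transporter SLC7A11 (2.51 and 0.50), GCLC (2.03 and 0.36) of glutathione synthesis, and HMOX1 (1.97 and 0.89), which degrades heme. With shASH2L-275, 22 rose and 1, OSGIN1, fell (-0.61), and with shASH2L-276, 24 rose and 0 fell. AKR1C1 has close paralogs, so its counts are uncertain. Lysosome and autophagy genes rose as well, 24 of 31 with 2 lower (median 0.29, camera adjusted p = 8.33e-10, adjusted p = 0.144 with an estimated correlation). GABARAPL1, of the autophagosome, changed by 2.20 and 1.15, and the lysosomal proteases CTSL and TPP1 by 1.84 and 1.17 with shASH2L-275 and 0.89 and 0.96 with shASH2L-276.

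Genes of DNA repair by homologous recombination fell in the comparison of both hairpins together, 28 of 28 (median -0.86, -1.25 with shASH2L-275 and -0.49 with shASH2L-276, camera adjusted p = 2.6e-14, adjusted p = 0.0623 with an estimated correlation). With shASH2L-275 alone 28 fell, and with shASH2L-276 alone 24 fell, 1 rose (FANCE, 0.19) and 3 did not pass (FANCM, PALB2 and RMI2). The helicase BRIP1 changed by -2.11 and -0.42, and FANCI, of crosslink repair, by -1.72 and -0.80. Of the 28 members, 4 are also in the S phase or G2/M lists. Genes of the COPI and COPII vesicle coats went both ways, 13 higher and 8 lower of 25 (camera adjusted p = 0.296, adjusted p = 0.594 with an estimated correlation). These lists were picked from the same data, so their p-values are not independent evidence.

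Genes whose 3' UTR holds TGGCAGA, CTGGCAG or ATGGCAG were higher with both hairpins together (z 5.83, 5.63 and 5.25, highest permuted 4.87). With shASH2L-275 their z was 4.01 to 4.27, none beyond the highest permuted 5.17, and with shASH2L-276 it was 5.07 to 5.95, with ATGGCAG within the highest permuted 5.20. Repression by the seed of the LacZ hairpin, which both knockdowns lack, may account for such a pattern. The z between the hairpins stayed within -0.424 and 0.313, but the words were picked as highest with both hairpins and the comparisons share the LacZ libraries, so the test does not decide it. The LacZ hairpin's sequence is not given in the sources used here.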
